A study of Mus musculus with 6 samples.

How the data were processed

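Expression was measured by RNA sequencing in 6 libraries of mouse retinal endothelial cell preparations, 3 control and 3 mutant, grouped by the genotype in the labels. Libraries were made from total RNA with a TruSeq RNA v2 kit, per the labels' protocols. The authors deposited FPKM values, 1 column per library and 24421 rows of gene symbols. Per the submitters' processing notes, the tools were STAR 2.5.0b, bedtools 2.17.0, Cufflinks 2.2.1 and DESeq2, on build mm10, with neither their order nor their roles given. Gene annotation, filters and strand use are not given in the sources used here.

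Gene symbols of 27 rows had become dates before deposit, 2 symbols were duplicated, 4518 rows were at 0 in all libraries, and 0 rows were mitochondrially encoded. Haemoglobin genes and Eno1, which every cell uses, were listed at or near 0, so a value of 0 can be a failed estimate. Positions came from GENCODE M21 on GRCm38, the assembly also called mm10, by symbol, for 95.6% of rows.

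Low FPKM values were whole multiples of what 1 read is worth. Depth was taken from 429 miRNA genes, of which 384 gave the same factor, and reads came out whole for all 16491 rows above 0 in every library (within 0.002 reads, rising to at most 0.05 for high counts). For rows with fewer values above 0 the match is not a strict test. The depth factors were 30864448, 24206403 and 25890347 reads in control replicates 1, 2 and 3 and 21062142, 31137829 and 27817342 reads in mutant replicates 1, 2 and 3. The factor was 1.0055 times a median-of-ratios depth in each library, so a further median-of-ratios scaling changes almost nothing. No pair of libraries within a group agreed within sampling noise, with chi-square per degree of freedom from 15.35 to 74.83. Counting error is small for genes with many reads and large for short loci with few.

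Differences were tested with limma 3.58.1 in R 4.3.3, with a trended prior on log2(FPKM + 1), for 13622 genes with at least 1 FPKM in at least 3 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The design also named count tests in case the values were counts. They are FPKM, so limma was used. Anxa3 was tested with an exact permutation test. Of 26 gene lists fixed before the data were examined, 23 had at least 3 tested members and went into camera with a preset correlation of 0.01, and then with an estimated correlation and into fry. The remaining 3 lists, erythroid and neutrophil genes, mitochondrially encoded genes, and the apelin alignment list, had too few. The erythroid and neutrophil level was 0.13 ± 0.02 in controls and 0.15 ± 0.04 in mutants on the log2 scale (SD, n = 3 each), and 0 mitochondrially encoded rows were present.

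Named genes were Anxa3 and all annexins, the largest changes among genes that passed (0 did), the 10 smallest unadjusted p in each direction, up to 4 members of each list with the smallest p, and Apln, Aplnr and Sfrp1. Other names are said to be chosen after their values were seen.

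The fit was tested on simulated data drawn from the real means, depths and spreads for the mutant against control comparison, over 13494 genes. It recovered 38% of genes changed 1.5-fold, 64.6% of those changed 2-fold, 91.8% at 4-fold and 100% at 8-fold, with 8 false calls. The simulated genes were drawn independently, and 5% of the unchanged ones had an unadjusted p under 0.05. In the real fit 1.21% of genes did, so the recovered shares need not hold for the real libraries. A count of 0 genes there does not exclude 2-fold changes. Alternatives fixed before the data were examined were another pseudocount (0.1), other filters, quantile and median-of-ratios normalization, a replicate block, library weights, a robust prior, a looser threshold (0.1) and the omission of each library. Added after the data were seen were an endothelial covariate, a block for sex make-up, a block for the letters of the libraries in the labels (A to C against D to F), the removal of short structural RNA and histone genes, total-read scaling, and limma voom on recovered reads, with and without quality weights. Camera with an estimated correlation was also added under each alternative. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used to recover reads, and matplotlib 3.10.9 for figures.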

Results

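RNA sequencing was carried out on endothelial cell preparations from the retinas of C57BL/6 mouse pups at postnatal day 7. Of the 6 libraries, 3 came from control pups with floxed Anxa3 alleles and 3 from mutant pups with the same alleles and Tie2-Cre, a recombinase expressed in endothelial and blood-lineage cells. The comparison asks which genes respond to the loss of annexin A3, a calcium-dependent phospholipid-binding protein, with the crossing of arteries and veins in mind. Only the mutants carry Cre, so an effect of Cre itself cannot be told apart from that of Anxa3 loss. Expression was given as FPKM, fragments scaled by gene length and library depth. The recovered reads ranged from 21386054 to 30904076 per library, and 13332 to 13695 genes reached 1 FPKM. Nothing in the labels says whether a library came from 1 pup or several, so p-values measure the spread between these libraries. The labels also letter the libraries: control replicates 1 and 2 and mutant replicate 1 are A, C and B, and control replicate 3 and mutant replicates 2 and 3 are D, E and F. What the letters stand for is not given.

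Anxa3 was lower in every mutant library than in every control library, and transcripts of the gene remained in the mutant libraries. It measured 18.7, 17.7 and 43.4 FPKM in control replicates 1, 2 and 3 and 9.78, 12.5 and 15.1 FPKM in mutant replicates 1, 2 and 3. The group means were 26.6 ± 14.6 FPKM in controls and 12.5 ± 2.66 FPKM in mutants (SD, n = 3 each). The mean of 20 pan-endothelial marker genes was 5.48 ± 0.59 in controls and 5.33 ± 0.18 in mutants on the log2(FPKM + 1) scale (SD, n = 3 each), and control replicate 3 stood at 6.16. Relative to that mean, Anxa3 was at -0.91, -0.85 and -0.69 in the controls and at -1.74, -1.54 and -1.52 in the mutants, a difference of -0.78 or 41.8% lower. The log2 difference in Anxa3 itself was -0.93, with a standard error of 0.323 and a limma 95% confidence interval from -1.68 to -0.19. Two-sided exact permutation tests of both differences gave p = 0.1, the smallest value that 20 arrangements allow. The limma adjusted p was 1, so Anxa3 did not pass among all genes. Without control replicate 3 the log2 difference was -0.53. Anxa3 was lower in mutants both among the libraries lettered A to C and among those lettered D to F, and with this division as a block the difference was -1.21 with a standard error of 0.168. Between 329 and 1795 reads lay behind each Anxa3 value. The gene lies on chromosome 5 from 96793339 to 96845966 on the plus strand of GRCm38, and values count reads over the whole gene, so exons outside the floxed part would still contribute.

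**Figure D1:**
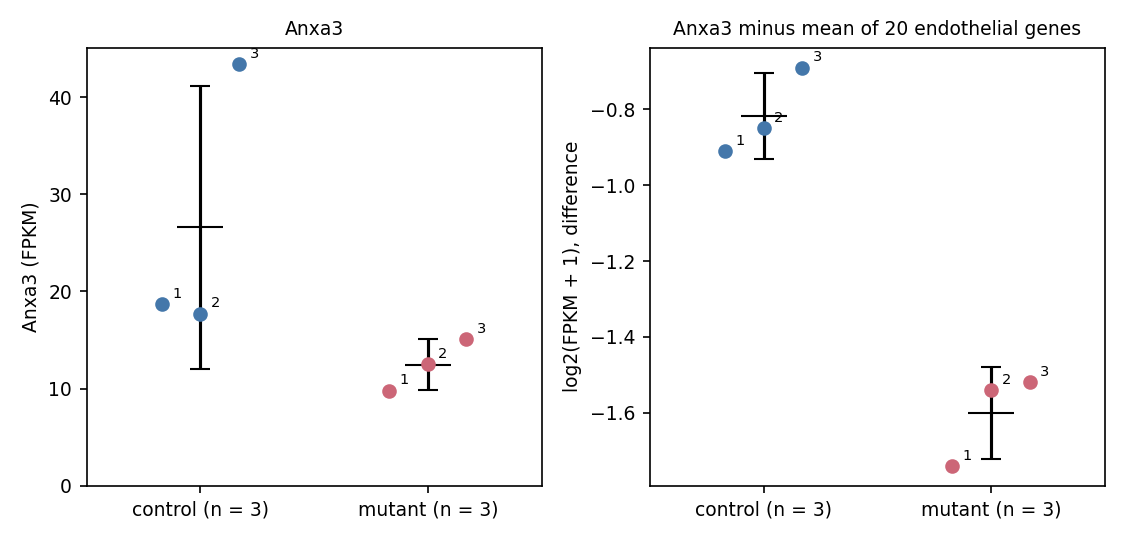
Anxa3 in each library. The left panel gives FPKM and the right panel gives log2(FPKM + 1) of Anxa3 minus the mean of 20 endothelial genes; points are libraries numbered by replicate, and bars are the mean and SD of 3 libraries. The controls lie at 17.7 to 43.4 FPKM and the mutants at 9.78 to 15.1 FPKM, with no overlap in either panel.

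The other annexins gave no call. Anxa2 measured 50.2 ± 17.4 FPKM in controls and 46.1 ± 7.53 FPKM in mutants, and Anxa6 49.4 ± 24.7 and 38.1 ± 10.2 FPKM (SD, n = 3 each). Log2 differences were 0.09 for Anxa1, -0.08 for Anxa2, -0.15 for Anxa4, -0.05 for Anxa5, -0.29 for Anxa6, 0.02 for Anxa7 and -0.03 for Anxa11. Anxa8, Anxa9, Anxa10 and Anxa13 fell under the expression filter. Of the 8 annexins tested, 0 passed over all genes and 0 when adjusted over the list alone. Signs turned when single libraries were left out, for Anxa2, Anxa5, Anxa6 and Anxa11 without control replicate 3, for Anxa1 and Anxa7 without control replicate 2, for Anxa2, Anxa5 and Anxa7 without mutant replicate 2, and for Anxa11 without mutant replicate 1. Differences over single omitted libraries ran from -0.05 to 0.31 for Anxa1, from -0.08 to 0.14 for Anxa7, from -0.23 to 0.18 for Anxa2, from -0.20 to 0.22 for Anxa5, from -0.50 to 0.08 for Anxa6 and from -0.16 to 0.20 for Anxa11.

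No gene changed between mutant and control libraries at a limma adjusted p under 0.05, among 13622 genes tested. The smallest adjusted p, 0.627, belonged to Sorcs2, a sortilin-family receptor, and the next was 1. At an unadjusted p under 0.05 there were 165 genes, 122 higher and 43 lower in mutants, against 681 expected by chance alone. Groups did not overlap for 593 genes, which is 4.4% against 10% by chance. On the recovered reads, limma voom called 0 genes, and voom with quality weights called 1, Sorcs2. Weights estimated per library, which ran from 0.26 for control replicate 3 to 7 for mutant replicate 2, raised the limma count to 145 genes, 125 higher and 20 lower. The first principal component, with 44.9% of the variance, parted the libraries lettered A to C from those lettered D to F. Marker levels parted the same way on the log2(FPKM + 1) scale. The pan-endothelial level was 5.08 to 5.21 in A to C and 5.29 to 6.16 in D to F. The photoreceptor level was 7.54 to 7.75 in A to C and 7.10 to 7.46 in D to F. Each of these sets holds 1 library of one genotype and 2 of the other, too few for a test within a set. With the division as a block, limma called 0 genes, with 927 at an unadjusted p under 0.05.

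Among the 10 genes with the smallest unadjusted p in each direction, none of which passed, the values with many reads lay mostly on the lower side. The wider set went the other way. Of 13007 genes outside the short structural RNA, miRNA and histone genes, 78 were higher and 18 lower in mutants at an unadjusted limma p under 0.05. Sorcs2 measured 20.3 ± 2.5 FPKM in controls and 10.4 ± 0.489 FPKM in mutants (SD, n = 3 each), a log2 difference of -0.90 with a standard error of 0.111. Zfyve28, which encodes a FYVE zinc finger protein, measured 12.1 ± 0.400 and 6.64 ± 2.44 FPKM, a log2 difference of -0.83 with a standard error of 0.232. Without mutant replicate 2 it was -0.54. Sox11, a transcription factor of neural progenitors, measured 10.3 ± 0.351 and 7.81 ± 0.904 FPKM. The noncoding gene Gm8013 measured 2.25 ± 0.222 and 1.16 ± 0.210 FPKM. The remaining genes with the smallest p on the lower side were Mir6371, Mir5620, Mir674, Mir7064, Mir7674 and AF357355. On the higher side they were Mir425, Mir1960, Snord99, Snhg9, Mir344e, Mir6934, Snord52, Snord71, Mir7087 and Gm20754, of which Mir425 measured 7.31 ± 0.822 FPKM in controls and 15.7 ± 3.06 FPKM in mutants from 15 reads in control replicate 3 to 44 reads in mutant replicate 2. Most of these are loci of short RNAs, for which few reads make a value imprecise.

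Sorcs2 lies on chromosome 5 from 36017180 to 36398139 and Zfyve28 from 34194893 to 34288449, both on the minus strand of GRCm38. The 21 tested genes between them had a median log2 difference of -0.06, from -0.38 to 0.20.

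**Figure D2:**
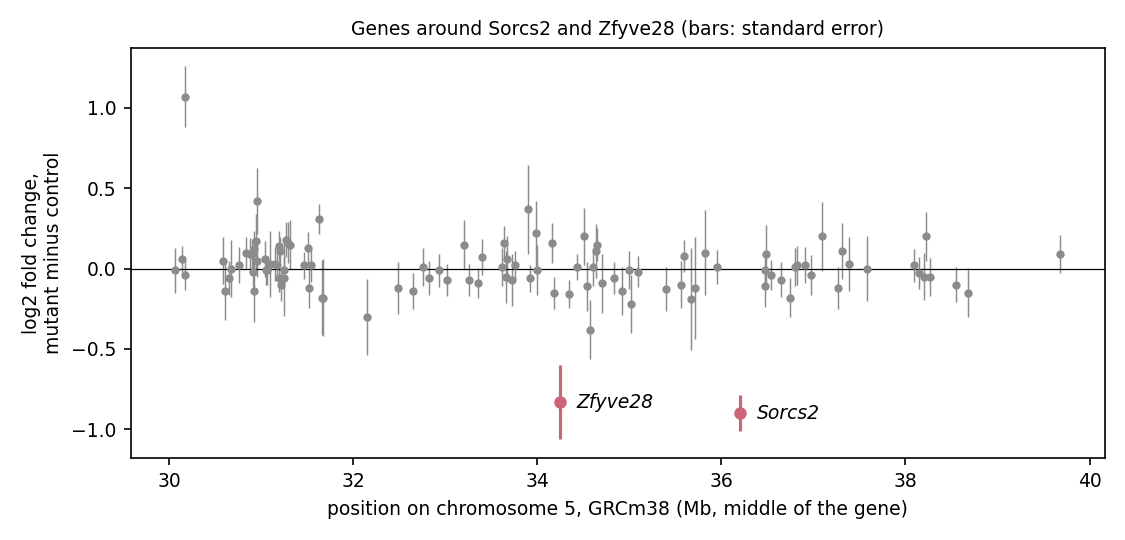
Log2 fold change, mutant minus control, of the 109 tested genes between 30 and 40 Mb of chromosome 5, placed at the middle of each gene; bars are standard errors and Sorcs2 and Zfyve28 are in colour. Sorcs2 at -0.90 and Zfyve28 at -0.83 lie below all other genes in the window, of which the lowest is at -0.38 and the highest, Mir1960, at 1.07.

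Endothelial and arterial gene groups had slightly lower means in the mutant group, and no member passed the test. The pan-endothelial level was 5.21, 5.08 and 6.16 in control replicates 1, 2 and 3 and 5.17, 5.29 and 5.53 in mutant replicates 1, 2 and 3. Only control replicate 3 lay above every mutant library. Exact permutation p was 0.9 for the pan-endothelial and 0.8 for the arterial level. All 20 pan-endothelial markers had a negative log2 difference, with a mean of -0.15, and the ETS factor Erg measured 12.3 ± 6.20 FPKM in controls and 9.32 ± 1.01 FPKM in mutants (SD, n = 3 each). The phosphatase Ptprb measured 36.1 ± 16.9 and 28.2 ± 1.78 FPKM. Of 18 arterial genes 16 were lower, with the chemokine receptor Cxcr4 at 15.4 ± 3.84 and 11.8 ± 1.27 FPKM, and of 20 tip-cell genes 16 were lower, with Lxn at 14.3 ± 5.48 and 10.3 ± 1.84 FPKM. All 15 Notch genes were lower, with Rbpj, the DNA-binding partner of Notch, at 9.14 ± 0.234 and 8.04 ± 1.46 FPKM. Of 16 BMP and TGF-beta genes 14 were lower, with Smad5 at 37.1 ± 5.06 and 32.3 ± 3.12 FPKM, and of 27 blood-retina barrier and Wnt genes 25 were lower, with Spock2 at 122 ± 47.6 and 93.4 ± 7.00 FPKM. With the preset correlation of 0.01, limma camera gave adjusted p = 0.016 for pan-endothelial, 0.0263 for arterial, 0.0268 for tip-cell, 0.0138 for Notch, 0.00566 for BMP and TGF-beta, and 0.00599 for barrier genes. With an estimated correlation none of these calls held, at adjusted p = 0.839 for each. Members passing were 0 over all genes and 0 when adjusted over the list alone, in each list tested. Control replicate 3 held 2.02 times the pan-endothelial level of control replicates 1 and 2, and the calls rested on single libraries. Without mutant replicate 1, 0 lists were called. Without control replicate 3 the list means lay above the mean of all genes, at 0.17 for pan-endothelial, 0.04 for arterial, 0.12 for tip-cell, 0.03 for Notch, 0.01 for BMP and TGF-beta and 0.11 for barrier genes. Of these, camera then called pan-endothelial (adjusted p = 3.37e-06), tip-cell (0.00539) and barrier genes (0.000309) higher in mutants. With the division by letter as a block, camera called 15 lists, 13 lower and 2 higher, at -0.35 for pan-endothelial genes, and control replicate 3 is the lone control in its set. With an estimated correlation 0 lists were called under each of 21 alternatives, with a smallest adjusted p = 0.51.

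Genes of vessel identity and alignment outside those lists gave no call in the designed limma fit, although several lists gained calls, in both directions, under alternatives. The venous list had 10 of 13 members lower (camera adjusted p = 0.0968), with the amino acid transporter Slc38a5 at 35.4 ± 13.9 FPKM in controls and 27.3 ± 3.84 FPKM in mutants (SD, n = 3 each). Camera called the venous list lower with voom (adjusted p = 0.0413), and without control replicate 3 it called it higher (0.09 above the mean of all genes, adjusted p = 0.0359). The apelin receptor Aplnr measured 78.2 ± 38.8 and 57.4 ± 10.1 FPKM, and its ligand Apln measured 29.7 ± 12.2 and 26.4 ± 8.40 FPKM, whereas Sfrp1 lay at 0.776 ± 0.266 and 0.629 ± 0.259 FPKM, under the filter. The Aplnr log2 difference of -0.35 became 0.03 without control replicate 3. Camera adjusted p was 0.208 for VEGF and angiopoietin signalling, with 9 of 12 lower and Nrp1 at 23.1 ± 7.37 and 18.9 ± 0.802 FPKM. It was 0.208 for guidance genes, with 15 of 21 lower, and 0.208 for extracellular matrix, with 20 of 24 lower. It was 0.362 for shear stress and YAP targets with 7 of 12 lower, 0.903 for proliferation with 11 of 24 lower, 0.843 for hypoxia and glycolysis with 8 of 16 lower, 0.385 for interferon response with 3 of 6 lower, and 0.128 for annexins with 6 of 8 lower. Without control replicate 3, camera called extracellular matrix (0.16, adjusted p = 2.8e-07), proliferation (0.12, adjusted p = 0.000234), shear stress (0.12, adjusted p = 0.00539) and VEGF genes (0.11, adjusted p = 0.018) higher in mutants. Without control replicate 2 it called the same 4 lists and the venous, annexin (adjusted p = 0.000389), guidance (adjusted p = 0.0297) and interferon lists (adjusted p = 0.0149) lower. The division by letter as a block gave lower calls for the venous (adjusted p = 0.00046), VEGF, guidance, extracellular matrix, shear stress and annexin lists. All of these calls used the preset correlation, and with an estimated one adjusted p was at least 0.51 for each. In hypoxia and glycolysis, the pyruvate dehydrogenase kinase Pdk1 measured 7.82 ± 0.384 and 6.45 ± 0.438 FPKM.

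Photoreceptor markers were abundant in all libraries, at a list level of 7.10 to 7.75 on the log2 scale, with Sag, chosen after its values were seen, at 772 to 1265 FPKM. Lens and pigment epithelium markers were low, at 0.71 to 1.29. Of 18 photoreceptor genes 15 were higher in mutants (camera adjusted p = 0.0554), with cone arrestin Arr3 at 17.5 ± 2.40 FPKM in controls and 21.6 ± 2.14 FPKM in mutants (SD, n = 3 each). Control replicate 3 held 0.71 times the photoreceptor level of control replicates 1 and 2. With the preset correlation camera called the photoreceptor list higher under 8 of 21 alternatives, among them voom (adjusted p = 0.021) and the division by letter as a block (adjusted p = 1.1e-08). With an estimated correlation these became adjusted p = 0.799 and 0.51. Without control replicate 3 the mean of the list lay at -0.08 from that of all genes. Microglia and macrophage markers were lower for 13 of 14 members (camera adjusted p = 0.0178, and adjusted p = 0.839 with an estimated correlation). The list level was 1.65 in mutant replicate 1 and 2.08 to 2.45 in the other libraries, and without mutant replicate 1 the list mean lay 0.08 above that of all genes. Pericyte and smooth muscle markers had 10 of 13 members higher (camera adjusted p = 0.208). With the preset correlation camera called them higher without control replicate 3 (0.30 above the mean of all genes, adjusted p = 1.21e-10), without mutant replicate 2 (0.15, adjusted p = 0.012) and with the endothelial mean as a covariate (0.17, adjusted p = 0.00029). With an estimated correlation these became adjusted p = 0.669, 0.908 and 0.966, and with the division by letter as a block the list lay at -0.03. Camera adjusted p was 0.303 for inner retinal neurons with 13 of 22 higher, 0.252 for Muller glia and astrocytes with 8 of 12 higher, 0.736 for lens and pigment epithelium, 0.284 for immediate early genes and 0.992 for sex-linked genes. The bipolar cell channel Trpm1 measured 17.5 ± 1.41 and 25.2 ± 7.35 FPKM.

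**Figure D3:**
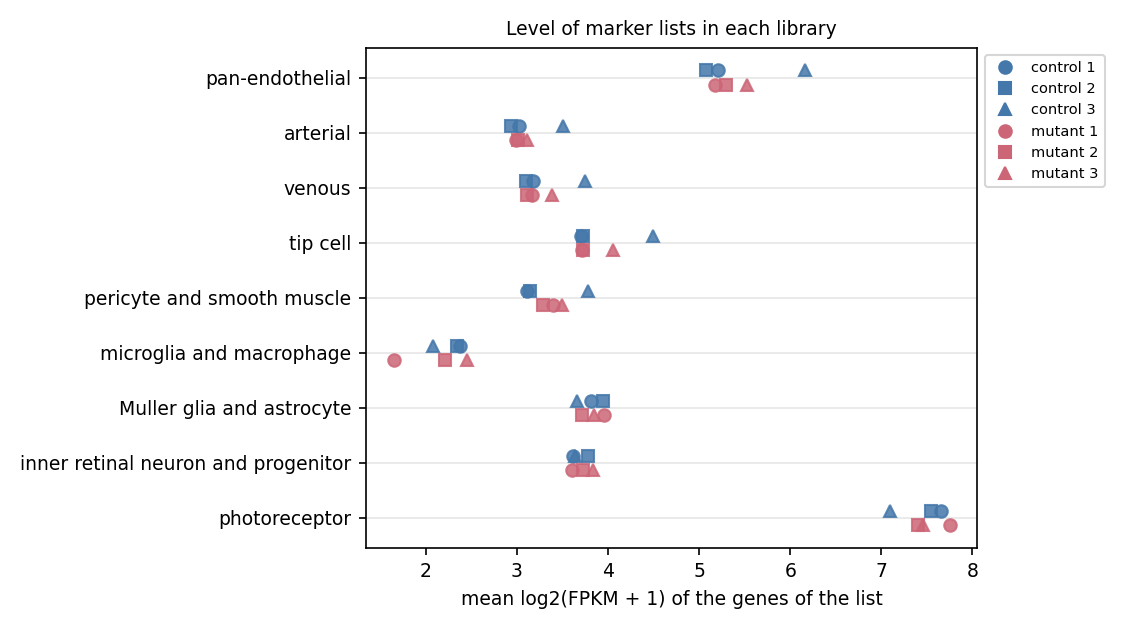
Mean log2(FPKM + 1) of 9 marker lists in each library; colours give the group and symbols the replicate. The photoreceptor list lies highest, at 7.10 to 7.75, and control replicate 3 has the highest pan-endothelial level, 6.16, and the lowest photoreceptor level, 7.10.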

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

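The covariate, sex block, letter block, gene-class, total-read and voom settings were chosen after the data were seen. The Anxa3 difference was negative under every alternative run, from -1.15 to -0.53 over single omitted libraries, and its adjusted p passed under none. The count of genes called was 0 except with library weights (145 genes) and voom with quality weights (1 gene, Sorcs2), and at an adjusted p under 0.1 it was 0. Library weights put 17 of 65 named genes past the threshold. The weighted fit also called up to 4150 genes on other splits of the 6 libraries. DESeq2 and edgeR were not run, since the deposited values are FPKM. The recovered reads were tested with limma voom instead, so no count-based test stands beside it. Same-numbered libraries deviated with correlations of 0.249, -0.151 and 0.391, and those with unlike numbers with -0.352 to 0.231. Not every library correlated best with its own number, and 3 libraries per group can neither show nor exclude pairing. With the replicate block 0 genes and 9 lists were called, and 296 genes had an unadjusted p under 0.05. The Anxa3 difference was -0.93 there with a standard error of 0.178. The added lists were annexin (-0.18, camera adjusted p = 0.0296) and venous (-0.12, camera adjusted p = 0.0187). The count of lists called was 7 and became 2 without a filter, 0 with library weights, 1 with the endothelial covariate (pericyte and smooth muscle, higher in mutants and none of the 7), 0 with voom and quality weights, 15 with the letter block, 0 with fry, and 0 with camera and an estimated correlation, alone or with each of 21 alternatives. The endothelial covariate is the mean of the pan-endothelial list itself, so the loss of that call was fixed in advance. The tip-cell, BMP and TGF-beta, and barrier lists share genes with it and were drawn the same way. Over single omitted libraries the count of lists called ran from 0 to 17: 13, 17 and 10 without control replicates 1, 2 and 3, and 0, 5 and 16 without mutant replicates 1, 2 and 3. Without control replicate 3, 9 of the 10 were higher in mutants. Of the 16 lists not called in the designed fit, 15 were called under at least 1 alternative with the preset correlation, and 8 of the 23 lists were called in both directions. The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 0 genes and 7 lists. Each of the 9 other splits gave more lists, from 8 to 19, so the count of lists does not set genotype apart. The highest gene count among the others was 19, in a split with 14 lists. The split of control replicates 1 and 2 and mutant replicate 1 from the rest, which is that of letters A to C from D to F, gave those 19 genes and 3795 genes at an unadjusted p under 0.05, which points to a structure of the samples apart from genotype. The same split also parted the libraries by pan-endothelial and photoreceptor level, and it cannot be told apart from one in tissue make-up. As a block it left 0 genes, 927 at an unadjusted p under 0.05 and 15 lists, against 0 genes, 117 to 258 and 0 to 15 with the other splits as blocks. The place of this division was chosen after the values were seen, which favours a small residual spread. With it hypoxia was at 0.01, pericyte and smooth muscle at -0.03, Anxa7 at -0.05 and Alas2 at 0.10. List values that follow are mean log2 differences of members less that of all genes, and signs turned as listed. With library weights they were 0.12 for pan-endothelial, 0.06 for VEGF and angiopoietin signalling, 0.04 for barrier and Wnt, 0.04 for shear stress, 0.01 for proliferation, 0.02 for interferon response, -0.14 for photoreceptor, -0.03 for inner retinal neuron, -0.19 for Muller glia and -1.97 for sex-linked genes. Single genes that turned there were Anxa2 at 0.00, Anxa11 at 0.17, Erg at 0.11, Ptprb at 0.06, Clu at -0.07, Apln at 0.02, Nrp2 at 0.06 and Crybb3 at 0.07. With voom and quality weights they were 0.08 for pan-endothelial, 0.02 for VEGF and angiopoietin signalling, 0.05 for barrier and Wnt, 0.04 for shear stress, 0.02 for proliferation, 0.12 for interferon response, -0.12 for photoreceptor, -0.19 for Muller glia and -2.46 for sex-linked genes. Anxa2 was at 0.02 there, Anxa11 at 0.20, Erg at 0.05, Ptprb at 0.01, Apln at 0.06, Nrp2 at 0.02 and Crybb3 at 0.04. With the endothelial covariate they were 0.01 for VEGF and angiopoietin signalling, 0.03 for extracellular matrix, 0.01 for shear stress, 0.05 for proliferation, 0.00 for interferon response, 0.04 for Anxa2, 0.06 for Anxa5, 0.07 for Anxa11 and 0.02 for Apln. Proliferation and hypoxia turned with a pseudocount of 0.1 (0.01 and 0.00), with voom (0.00 and 0.01) and without short RNA and histone genes (0.00 and 0.00), hypoxia without a filter (0.00) and interferon response with voom (0.04). Over single omitted libraries the lists whose sign turned ran from -0.32 to 0.05 (annexin), -0.35 to 0.17 (pan-endothelial), -0.22 to 0.04 (arterial), -0.25 to 0.09 (venous), -0.26 to 0.12 (tip cell), -0.23 to 0.03 (Notch), -0.21 to 0.01 (BMP and TGF-beta), -0.20 to 0.11 (VEGF and angiopoietin), -0.28 to 0.11 (barrier and Wnt), -0.13 to 0.03 (guidance), -0.20 to 0.16 (extracellular matrix), -0.21 to 0.12 (shear stress), -0.07 to 0.12 (proliferation), -0.07 to 0.04 (hypoxia), -0.18 to 0.08 (interferon), -0.05 to 0.30 (pericyte), -0.08 to 0.22 (photoreceptor), 0.00 to 0.10 (inner retinal neuron), -0.05 to 0.13 (Muller glia), -0.38 to 0.08 (microglia), -0.25 to 0.16 (lens and pigment epithelium) and -0.84 to 0.90 (sex-linked). Genes whose sign turned ran from -0.05 to 0.31 (Anxa1), -0.23 to 0.18 (Anxa2), -0.20 to 0.22 (Anxa5), -0.50 to 0.08 (Anxa6), -0.08 to 0.14 (Anxa7), -0.16 to 0.20 (Anxa11), -0.49 to 0.09 (Erg), -0.49 to 0.09 (Ptprb), -0.60 to 0.03 (Aplnr), -0.37 to 0.17 (Apln), -0.36 to 0.00 (Nrp2), -0.39 to 0.04 (Col18a1), -0.29 to 0.04 (Ifitm3), -0.02 to 0.27 (Myl9), -0.39 to 0.07 (Alas2) and -0.65 to 0.00 (Pmel). Apart from the smaller number of libraries or genes, the cause was not tested. Short loci with few reads are limited by depth.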

Other observations

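The tests in this part were chosen after the results were seen, except that the omission of single libraries was among the alternatives fixed beforehand. The sex make-up of the libraries was read from Xist and the Y-linked gene Eif2s3y, and it was balanced between the groups. Control replicate 1 and mutant replicate 2 had Xist at 257 and 329 FPKM with Eif2s3y at 0 and 0.0181 FPKM. Control replicate 3 and mutant replicate 1 had Xist at 0.136 and 0.339 FPKM with Eif2s3y at 54.9 and 50.9 FPKM. Control replicate 2 and mutant replicate 3 held both, with Xist at 93.5 and 118 FPKM and Eif2s3y at 28.0 and 30.3 FPKM, as a pool of male and female tissue would. A block for this make-up left the count at 0 genes.

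Gm8013 is a long noncoding RNA gene on chromosome 5 from 96921272 to 96934867, 75.3 kb past the end of Anxa3 on the same strand. Its log2 difference was -0.59 with a standard error of 0.144, and it did not pass the adjusted threshold. It was lower in 3 of 3 mutant libraries, from 24 to 30 reads in each control and 9 to 19 in each mutant library. The gene was named for its small unadjusted p, so this lack of overlap is no separate support.

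Anxa3 was lower in the mutant libraries, and 2 technical accounts were set against deletion by Cre. A lower endothelial share is argued against as the whole account, since Anxa3 relative to 20 endothelial markers still differed by -0.78 on the log2 scale, with SDs of 0.12 in both groups. The endothelium-rich control replicate 3 is argued against as the whole account, since without it the difference was -0.53 with a standard error of 0.166 and no overlap. With the endothelial mean as a covariate, Anxa3 had rank 1 by p among 13622 genes, although its adjusted p there was 0.309, within a range of 0.068 to 1 over the alternatives. These values are in line with removal of the gene in part of the cells, as a hypothesis, and what share of the remaining transcripts comes from cells without Cre was not tested.

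Sorcs2 and Zfyve28, 60.4 and 62.5 Mb from Anxa3 on the same chromosome, were both lower in 3 of 3 mutant libraries, though neither passed the adjusted threshold. A lower endothelial share is argued against, since with the endothelial covariate Sorcs2 stayed at -0.90 (standard error 0.111) and Zfyve28 at -0.82 (standard error 0.235), although Zfyve28 was at -0.54 without mutant replicate 2. A change of the whole segment is argued against, since the 21 genes between them had a median of -0.06 with an SD of 0.14. A segment of another strain next to the floxed alleles would be shared by both groups, since controls carry the same alleles. Such a segment elsewhere on chromosome 5 stays open. Over the whole chromosome, 14 of 837 other genes had an unadjusted p under 0.05 against 137 of 12272 elsewhere (odds ratio 1.51, 95% interval 0.80 to 2.63, Fisher's exact p = 0.176, with neighbouring genes not independent). A count over the whole chromosome can neither show nor exclude a short segment. A chance pair, an effect of Anxa3 loss and one of Cre itself stay open as well. Among 9 other splits of the libraries the smallest unadjusted limma p of any gene went down to 1.36e-06, below the 4.61e-05 of Sorcs2. That value came from the split of letters A to C from D to F, which has a structure apart from genotype. With control replicates 1 and 2 and mutant replicate 2 set against the rest, the smallest unadjusted limma p was 3.88e-06. These values are for single genes and do not test a pair on the same chromosome.

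Histone genes had a mean of 3.97 ± 0.27 in controls and 4.28 ± 0.35 in mutants on the log2 scale (SD, n = 3 each, exact permutation p = 0.2), at 3.89, 3.75 and 4.27 in control replicates 1, 2 and 3 and 3.91, 4.33 and 4.61 in mutant replicates 1, 2 and 3. For 103 small nucleolar and Cajal body RNA genes the values were 3.58, 3.55 and 3.89 in controls and 3.35, 4.15 and 4.05 in mutants, a difference of 0.18 with an exact permutation p = 0.6. The lowest of the libraries lettered D to F lay above the highest of A to C by 0.36 for histone and 0.31 for small nucleolar RNA genes. With that division as a block, the differences between mutants and controls were 0.14 (standard error 0.12) and 0.00 (standard error 0.13). The place of the division was chosen after the values were seen, so neither the gaps nor the blocked differences test it independently. Ribosomal protein genes did not part by letter, with a gap of -0.18. Of 79 such genes 68 were higher in mutants, but 0 had an unadjusted limma p under 0.05. Their class mean differed by 0.10 between mutants and controls, with an exact permutation p = 0.3. An effect of the genotype cannot be told apart from that of the division with 3 libraries per group, and what the letters stand for is not given.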
